A study of Caenorhabditis elegans with 2 samples.

How the data were processed

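Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole young adult Caenorhabditis elegans, collected at 64 hours, of a transgenic strain that carries a SEA-2 fusion to GFP and an unc-119 rescue gene. The precipitation used an antibody against GFP, per the description labels, while the antibody label itself names sea-2. The 2 biological replicates form 1 group, and no comparison group was analysed here.

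The authors deposited 8 peak lists on the ce11 assembly, which is the WBcel235 sequence. Each replicate has a ranked list of candidate peaks and a thresholded list, and the pooled replicates have 2 ranked lists, an optimal thresholded list and a smaller conservative thresholded list. The deposited signal of a peak is the authors' own peak caller value; its scale and any normalisation between lists are not given in the sources used here. The deposited lists also hold -log10 q values and the -log10 irreproducible discovery rate (IDR), a measure of how far a peak's rank repeats between compared lists. The p column of the lists held a single value, -1, and was not used. Aligner, peak caller and their versions are not given in the sources used here, and neither are read depths, so the depth of each replicate is unknown.

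The thresholded lists were compared with the ranked lists before use. Every peak of a thresholded list was a candidate at an IDR of 0.01 or less, and 70 of the 523 candidates of the pooled list at that threshold were absent from the optimal list. For the conservative list this was 63 of 494, for replicate 1 38 of 205 and for replicate 2 61 of 180. A step that removes listed regions is inferred from these counts and is not stated in the sources used here. The ranked list of true replicates was recognised by the peak half-widths of the lists it compared, 148 and 140 bp, which were also the half-widths in the lists of replicates 1 and 2.

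Peaks with summits within 200 bp of a stronger kept summit were dropped, leaving distinct peaks. The background was every unselected candidate of the longer pooled ranked list, which contained every optimal peak, without the removed candidates. By this rule 102 distinct peaks of the conservative list that the optimal list lacks stood in the background. Summits were assigned to the Ensembl annotation of WBcel235. A promoter summit lay from 1000 bp upstream to 200 bp downstream of the start of a protein-coding gene, and other summits were classed as exon, intron or intergenic. A summit within 500 bp of a tRNA, snRNA, snoRNA, rRNA or miRNA gene counted as near it. No peak extended past the end of its chromosome in the reference.

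Shares were compared by two-sided Fisher's exact tests on peaks, with Benjamini-Hochberg adjustment within chromosomes, locations, non-coding classes, 18 gene lists or 2080 6-mers (both strands pooled, presence within 100 bp of the summit). Intervals of shares are exact 95% Clopper-Pearson intervals. Odds ratios with intervals are conditional maximum likelihood estimates with exact 95% intervals, unlike the sample odds ratios of the gene lists. Both kinds of interval cover counting error only. Intervals of locus percentiles are 95% bootstrap intervals over candidates. GC content was compared by a two-sided permutation test with 100000 resamples. Peaks are not independent biological replicates, so these p-values describe peak sets from the same animals. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

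The tests were tested on simulated selections of candidates. A random selection gave 0 called 6-mers of 2080. With 20 planted 6-mers, each put into 15% of the selected windows, 19 were recovered, and 60 other 6-mers were called, of which 60 overlapped a planted 6-mer by 4 or 5 bases, so called 6-mers are not independent. Of 100 random selections, 5 passed the unadjusted threshold of 0.05 for the promoter share, 2 for the tRNA share, and 4 called any gene list.

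The gene lists, tests, backgrounds, the rule for named genes and the alternatives given here were fixed before the data were examined. The rule named the nearest protein-coding gene start of the 15 distinct optimal peaks with the highest signal, listed genes with a peak in their promoter window (up to 5 per list, by signal), xol-1, lin-28, sea-2 and unc-119, and the 3 strongest peaks on X. Alternatives were the conservative list, the peaks at or above the median signal, every peak as deposited, each replicate's own list, other windows, distances and overlaps, and other backgrounds. Alternatives added later are named as such in the closing section.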

Results

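The series measured where SEA-2, a zinc finger protein known as an autosomal signal element of sex determination and as a regulator of the heterochronic gene lin-28, was found on chromatin of young adult worms. The optimal list of the pooled replicates held 453 peaks, of which 445 were distinct, and the conservative list held 431, a ratio of 1.05. Replicate 1 alone gave 164 distinct thresholded peaks and replicate 2 gave 118, and as deposited the list of replicate 1 was 1.40 times as long. Signal in the optimal list had a median of 93.7 and ranged from 2.28 to 394.9, against a median of 24.9 over the 82563 candidates. In the optimal list 228 peaks had a q value above 0.05, and 23 had a signal under the candidates' median.

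The replicates selected overlapping regions far more often than their unselected candidates did. Of the 164 distinct peaks of replicate 1, 69 (42.1%, 95% interval 34.4 to 50.02%) overlapped a thresholded peak of replicate 2 by at least 1 bp, against 0.109% of 50488 unselected candidates (Fisher's exact test, two-sided, p = 5.0e-144). Of the 445 distinct optimal peaks, 70 overlapped thresholded peaks of both replicates and 241 overlapped those of neither. Signal ranks across all candidates were weakly related between replicates, with a Spearman's rho of 0.208 and a Pearson's r of 0.246 on log10 values, across peaks that are not independent replicates. Over the thresholded peaks rho was 0.291, and over the candidates with signal in the upper part of the list, split at the median, it was -0.0437; choosing peaks by IDR or by pooled signal can itself move this correlation.

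Of the 15 strongest distinct peaks 7 lay in promoter windows, and all 15 overlapped thresholded peaks of both replicates. The highest signal, 394.9, was on chromosome III at 10759159 to 10759362 (ce11), with its summit 46 bp upstream of tasp-1, which encodes a threonine aspartase. Promoter peaks followed 629 bp upstream of rpa-2 (signal 311), 161 bp upstream of F44E5.4, a member of the Hsp70 family (305), 282 bp upstream of the ribosomal protein gene rpl-3 (253), 242 bp upstream of mog-4, a helicase gene known from the germline sperm-oocyte decision (241), 351 bp upstream of rpl-15 (231) and 625 bp upstream of tag-340 (215). Intergenic peaks lay nearest to K08F11.1, at signals of 339 and 334, to C46C2.7 (248) and to Y106G6H.9 (209). Intronic peaks lay in frm-7, inside the snoRNA gene C51F7.4 (316, nearest start F55C5.17), in the peroxidasin gene pxn-1 beside a snoRNA gene (279), in the kinase gene cmk-1 (262, nearest start ccm-2) and in ints-8, inside the RNase P RNA gene rpr-1 (206).

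Peaks were concentrated at promoters and depleted from exons. Promoter windows held 176 of 445 summits (39.6%, 95% interval 35.0 to 44.3%), against 20.8% of 80424 unselected candidates (Fisher's exact test, two-sided, adjusted p = 1.4e-18). Exons held 12.4% against 30.03% (Fisher's exact test, adjusted p = 4.1e-18). Introns held 24.7% against 27.8% (adjusted p = 0.203) and intergenic sequence 23.4% against 21.3% (adjusted p = 0.296), differences that did not pass the exact test. The promoter share of candidates was near the 21.5% of genome bases that such windows cover. Without another precipitation, binding by SEA-2 cannot be told apart from a general affinity of open chromatin.

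Genes of small structural RNAs carried a large excess of peaks. Of the 445 summits, 51 (11.5%, 95% interval 8.65 to 14.8%) lay within 500 bp of a tRNA gene, against 0.791% of unselected candidates (Fisher's exact test, adjusted p = 3.3e-40), and 60 of 612 annotated tRNA genes had such a peak. Near snoRNA genes, whose RNAs guide RNA modification, lay 33 summits (7.42% against 0.480%, Fisher's exact test, adjusted p = 3.2e-27). Near snRNA genes, which include those of spliceosomal and spliced leader RNAs, lay 11 (2.47% against 0.141%, Fisher's exact test, adjusted p = 2.0e-10). With a single replicate's list the snoRNA share was 12.7% without replicate 1 and 11.6% without replicate 2, and the snRNA share 2.54% and 4.27%. The rRNA genes had 2 peaks, both at the same gene, rrn-4.15, against 5 background candidates (Fisher's exact test, adjusted p = 0.000779), and miRNA genes had 3, which did not pass (Fisher's exact test, adjusted p = 0.169). Of the tRNA-associated summits 29 lay inside the gene.

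**Figure D1:**
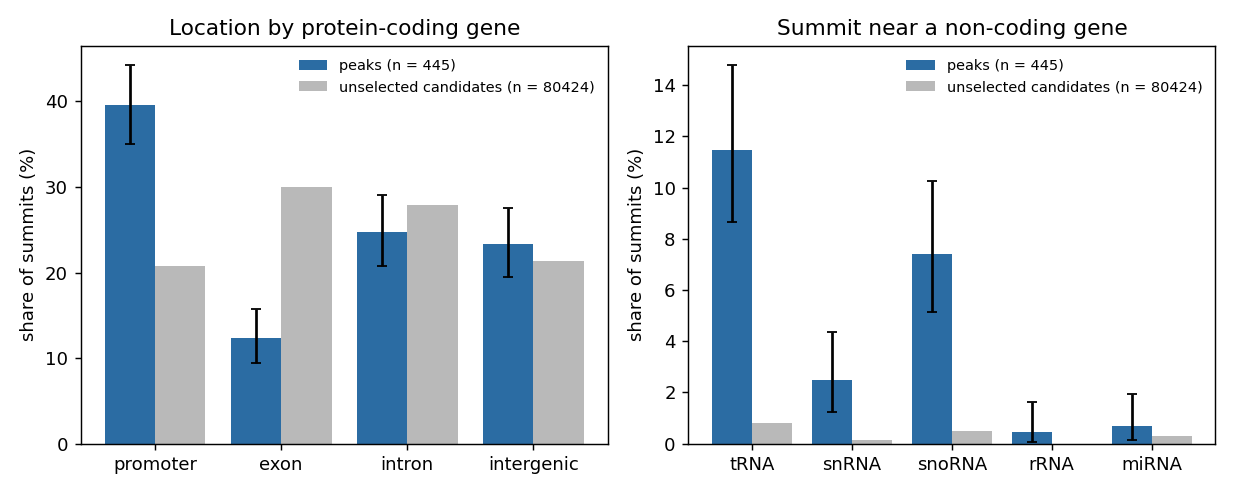
Share of summits (%) by location relative to protein-coding genes (left) and within 500 bp of non-coding genes (right), for 445 distinct optimal peaks and 80424 unselected candidates; error bars are exact 95% intervals. Promoters held 39.6% of peaks against 20.8% of candidates, and tRNA genes 11.5% against 0.791%.

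Chromosome X, whose dose the sex determination pathway measures, was not detectably enriched. It held 88 of 445 peaks (19.8%, 95% interval 16.2 to 23.8%), against 18.4% of unselected candidates (Fisher's exact test, two-sided, p = 0.461, adjusted p = 0.692). None of the 6 chromosomes passed the test. Most of the 51 peaks near tRNA genes lay on X, and the X share of the other peaks was not tested. The share on X therefore need not hold for peaks away from tRNA genes. With replicate 2's own list the share on X was 26.3% against 17.9% (Fisher's exact test, unadjusted p = 0.0220, adjusted p = 0.132). With replicate 1's list it was 19.5% against 18.8% (Fisher's exact test, adjusted p = 0.841). Between the replicates' shares Fisher's exact test gave p = 0.194. This test takes the lists as independent, but 68 of replicate 2's 118 peaks overlapped replicate 1's list, so it cannot decide whether the shares differ. The strongest X peaks were at 11094036 to 11094339 (intergenic, signal 184, nearest start W02H3.3), at 9743508 to 9743811 (166, nearest start F15G9.5, in an intron of the hemicentin gene him-4 and over a tRNA gene) and at 14818833 to 14819136 (165, 471 bp upstream of the epsin gene epn-1).

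**Figure D2:**
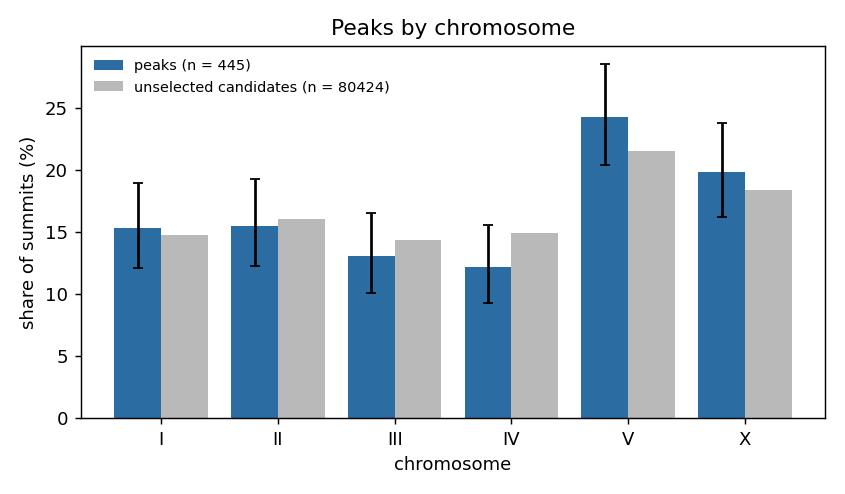
Share of summits (%) on each chromosome for 445 distinct optimal peaks and 80424 unselected candidates; error bars are exact 95% intervals. X held 19.8% of peaks and 18.4% of candidates.

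Of the 18 gene lists, 3 held more promoter peaks than unselected promoter candidates. The ribosomal protein list held 10 of 176 promoter peaks (5.68% against 0.585%, odds ratio 10.2, Fisher's exact test, adjusted p = 3.3e-06). Among them were those at rpl-3, rpl-15, rpl-35 (signal 173), rpl-20 (157) and rps-26 (144). The list lacked rpl-7A, whose promoter peak 62 bp upstream (148) overlapped thresholded peaks of both replicates. The summits at rpl-20 and rps-26 lay nearer to the starts of Y17G9B.5 and tmem-107. For the ribosomal protein list the odds ratio was 21.6 from 5 peaks without replicate 1 and 15.8 from 7 peaks without replicate 2. The heat shock and DnaJ list held 6 (3.41% against 0.287%, odds ratio 12.3, Fisher's exact test, adjusted p = 0.000179). These lay at dnj-13 (146), the endoplasmic reticulum chaperone hsp-3 (133), dnj-28 (114), hsp-1 (110) and the mitochondrial chaperonin hsp-60 (106). The list lacked F44E5.4, the Hsp70 family gene whose stronger promoter peak (305) overlapped thresholded peaks of both replicates. The hsp-60 summit lay nearer to the start of Y22D7AL.10. The 6 peaks lay at 5 genes, since dnj-28 had a second summit with a signal of 8.44, and by gene the odds ratio was 9.76 (Fisher's exact test, adjusted p = 0.00278). For this list, with replicate 2's own list 1 such peak was left and the call was lost (odds ratio 5.69, Fisher's exact test, adjusted p = 0.754), and with replicate 1's the odds ratio was 25.8 (adjusted p = 3.3e-05). Genes off the heterochronic list, and peaks outside promoter windows such as those in lin-42 introns (111, 91.2 and 8.73), were not counted for it. That list held 3 (1.70% against 0.125%, odds ratio 13.8, Fisher's exact test, adjusted p = 0.0115). The 3 lay at nhl-2 (215, in the window shared with tag-340), lin-66 (79.0) and puf-9 (79.0). This call rested on few peaks and was lost with the conservative list (odds ratio 4.46, Fisher's exact test, adjusted p = 0.626), with peaks at or above the median signal (8.65, adjusted p = 0.517), with replicate 1's own list (8.89, adjusted p = 0.680) and with the narrower window, where the odds ratio was 13.04 (adjusted p = 0.0614). With replicate 2's own list it passed, with an odds ratio of 25.7 from 2 peaks (Fisher's exact test, adjusted p = 0.0318).

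Histone genes had 3 promoter peaks, at his-61 with his-62 (106), his-37 (96.6) and his-5 with his-6 (70.3), and did not pass (Fisher's exact test, adjusted p = 0.0720). Single peaks lay at the actin gene act-4 (96.2) and at unc-42, a homeobox gene of neurons (86.7). Another lay at ifet-1 of the translation factor list (116), a summit shared with rps-1 and nearer to it. Nuclear hormone receptor genes had 2, at nhr-141 (84.6) and nhr-255 (74.9). The muscle, homeobox, translation factor and nuclear hormone receptor lists did not pass the test. The sex determination and dosage compensation list had 0 of 176 promoter peaks, against 0.125% of candidates (Fisher's exact test, adjusted p = 1), and 0 peaks were also found for insulin signalling, collagens, major sperm proteins, the proteasome, germline, intestine, neurons, epidermis and pharynx. The candidates' share in these lists was at most 0.890% (collagens). With shares this small, 0 of 176 peaks cannot show a depletion.

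Neither xol-1 nor lin-28 carried a thresholded peak in its body or promoter window; lin-28 is known to be regulated by SEA-2 through its mRNA. In xol-1, the sex determination switch gene (X, 8041313 to 8044409), the strongest candidate had a signal of 34.6 and ranked 20896 of 80944. Its promoter window held 0 candidates. In the body of lin-28 (I, 8407630 to 8410804) the strongest had 26.01 and ranked 38708, and in its promoter window the strongest had 31.02 and ranked 27484. The lists start from candidates above a minimum, so this does not show that binding was absent. Only whole young adults were sampled, so binding at other stages or in a few cells was not addressed. The same limit holds for the X share and for the sex determination list.

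The strain carries added copies of sea-2 and unc-119. The body of sea-2 (II, 3950377 to 3972140) held 7 optimal peaks in introns and exons, the strongest at 3957897 to 3958200 with a signal of 95.2, ranking 271 of 80944 candidates. Replicate 1 had 3 thresholded peaks there and replicate 2 had 4. Of the 7 optimal peaks, however, 0 overlapped those of both replicates, 2 overlapped those of replicate 1 only, 3 those of replicate 2 only and 2 those of neither. The 7 are not all separate regions. The peak at 3964384 to 3964687 overlaps that at 3964616 to 3964919, both counted for replicate 2 only. The peak at 3968608 to 3968911 overlaps that at 3968828 to 3969131, both counted for neither. The body of unc-119 (III, 10902641 to 10908935) held 0 optimal peaks, and its strongest candidate had a signal of 53.4 and ranked 3688.

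**Figure D3:**
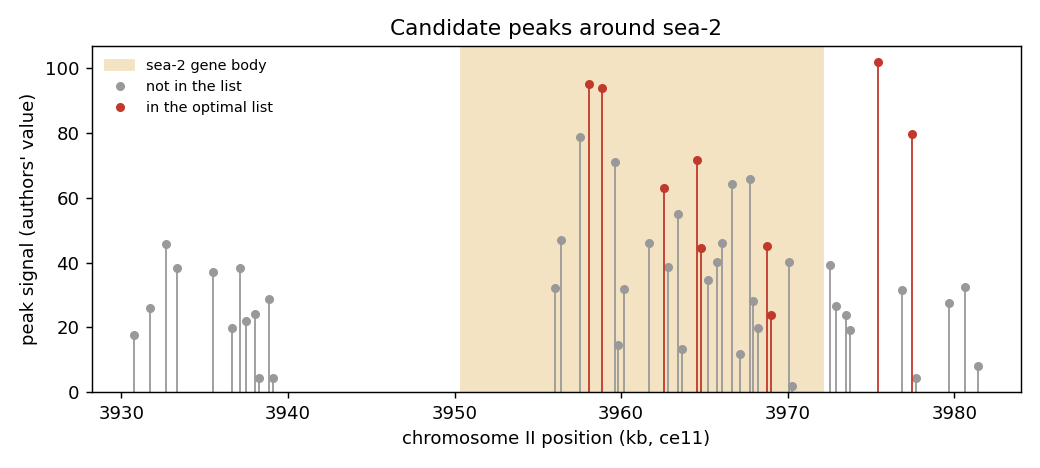
Signal of each distinct candidate peak (authors' value, vertical axis) by position on chromosome II (kb, ce11) over sea-2 with 20 kb on each side; the shaded span is the gene body and red points are optimal peaks. The gene body held 7 optimal peaks and the flanks 2.

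Peak sequence was richer in G and C than that of unselected candidates. GC content within 100 bp of the summit averaged 49.1% ± 7.13 (SD, n = 445) in peaks and 40.1% ± 7.08 (SD, n = 80424) in candidates, a difference of 9.09 points (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples give). Of 2080 6-mers, 512 were more frequent in peaks and 428 less frequent. A CG dinucleotide was held by 307 of the 512, by 15 of the 428 and by 604 of all 2080. CGCGCA was present in 18.4% of peaks against 3.93% of candidates (Fisher's exact test, adjusted p = 1.4e-27), and GAGAGA, without CG, in 27.9% against 11.7% (Fisher's exact test, adjusted p = 2.8e-18). With GC-matched candidates 183 6-mers were more frequent in peaks.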

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

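The tests on abundant transcription and on added DNA copies were chosen only after related values had been seen. No explanation that rests on a comparison of groups was tested, since the design has 1 group.

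Candidates that met the IDR threshold but are absent from the optimal list were looked at because the comparisons do not use them. There were 70, and the strongest, on X at 15810995 to 15811177, had a signal of 2113, above the 394.9 of the strongest optimal peak. In 64 of the 70 (91.4%) more than 50% of the 31-mers around the summit recurred in the nuclear genome, against 11.2% of distinct optimal peaks, and 61 of the 70 were intergenic.

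Peaks near tRNA, snoRNA and snRNA genes numbered 95 of 445. Against GC-matched candidates their odds ratio was 14.4 (95% interval 10.8 to 19.02), which argues against GC content as the whole cause, although matching left the candidates at 48.2% against 49.1%. Among windows with under 10% repeated 31-mers the odds ratio was 13.3 (9.07 to 19.1). This argues against multi-copy sequence as the whole cause for these classes pooled, though 59 of the 95 peaks lay in windows with more repeats. The classes were not split, and 49 of the 51 tRNA-associated summits lay within 100 bp of the gene. The test therefore does not settle the tRNA peaks on their own. Promoters of collagen, major sperm protein, intestine and muscle genes gave an odds ratio of 0.390 (0.00977 to 2.22) from 1 peak. Whether these genes were heavily transcribed in the animals sampled was not tested. Lists outside this test went both ways. Ribosomal protein genes had an odds ratio of 10.2 and heat shock and DnaJ genes 12.3, and both passed. Translation factor genes had 2.51, which did not pass, and proteasome genes had 0 of 176 promoter peaks. With so few peaks and no measure of transcription, abundant transcription cannot be told apart from binding. A general affinity of open or heavily transcribed chromatin for precipitation remains open, as no other precipitation was analysed here. This holds for the promoter and gene list results as well.

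The 7 optimal peaks in the body of sea-2 may come from added DNA copies of the transgene. The median signal of unselected candidates over the gene with 20 kb on each side was at the 98.4th percentile of 1604 windows of that length, with a bootstrap interval from 37.9 to 99.9, so the explanation cannot be told apart from local binding with 41 candidates. The gene body alone, looked at after these values, had a median of 39.4, at the 99.8th percentile of windows of its length (88.3 to 100), and the flanks alone 25.97, at the 59.5th (4.76 to 96.9), against 25.003 over unc-119 with its flanks. The body of unc-119 alone had a median of 33.5 from 4 candidates, fewer than the 10 required of a window, so it was given no percentile. The extent of the added DNA was not analysed here.

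The excess of GC-rich 6-mers was tested against GC content and small RNA genes. Against GC-matched candidates 183 6-mers were more frequent in peaks, of which 161 were among the 512, so GC content may account for a large part, and how much of the rest is left by incomplete matching cannot be told apart. Without peaks and candidates near small RNA genes 446 were more frequent in peaks, and 411 of these were among the 512, which argues against those genes as the cause.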

How the results depend on the processing

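The enrichment of promoters and tRNA genes and the GC difference kept direction and side of the threshold under every alternative run, as did the replicate overlap (38.4 to 57.6%). The number of distinct peaks was 227 at or above the median signal and 118 to 164 with a single replicate's list. The X share ran from 19.5 to 26.3% over single replicates and had an unadjusted p under the threshold only at the latter, without replicate 1 (Fisher's exact test, p = 0.0220, adjusted p = 0.132); the cause was not tested. The 6-mers more frequent in peaks numbered 216 to 252 with single replicates, where fewer peaks were tested, 183 against GC-matched candidates and 268 for promoter peaks alone; the cause of the latter was not tested. The correlation between replicates was 0.291 over thresholded peaks and -0.0437 over candidates at or above the median signal; both sets were chosen by values that the replicates make up, so neither shows a change in reproducibility. With 20 kb on each side the strongest signal was 102 at sea-2 and 53.7 at unc-119, by construction of the wider region. The number of gene lists passing was 2 to 4 over the alternatives. The histone list, which did not pass, had an odds ratio of 0 in either single replicate's list, from 0 peaks, and passed under 4 separate alternatives: genes as the unit (Fisher's exact test, adjusted p = 0.00464), the narrower window (adjusted p = 0.0202), the wider window (adjusted p = 0.00928) and small RNA genes left out (adjusted p = 0.0441). Alternatives leaving out small RNA genes, and tRNA genes against GC-matched candidates, were chosen after seeing the data. Read depth is unknown, which limits what the absence of a peak can show.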

Other observations

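The test of CGAACC below was chosen after the 6-mer had been seen among those most enriched in peaks. Its criterion was set before its result was seen. The genes in the first paragraph were chosen after their values were seen.

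A summit lay inside mrpr-1, the RNA of RNase MRP (signal 109, II, 7200103 to 7200406), as in rpr-1, the related RNase P RNA. Among the peaks counted near snRNA genes, those near spliced leader RNA genes lay at sls-2.4 (177), sls-2.1 (172), sls-2.2 (116) and sls-2.8 (108). In the sea-2 flank, peaks lay near cank-26 (102) and in dos-2 (79.7).

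CGAACC resembles part of the internal promoter of tRNA genes, so its excess in peaks could have come from tRNA genes alone. It was present in 16.6% of peaks and 4.71% of candidates. Without peaks and candidates within 500 bp of a tRNA gene it was in 10.9% of peaks and 4.41% of candidates, an odds ratio of 2.65 (95% interval 1.88 to 3.66), which argues against tRNA genes as the whole cause. Near tRNA genes it was in 60.8% of peaks and 41.8% of candidates. The candidates were not matched on GC content here, so how much of the remaining excess comes from GC content cannot be told apart.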
